A study of Mus musculus with 7 samples.

How the data were processed

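Polyadenylated RNA from the pancreas of mouse embryos at E15.5 was sequenced by the authors in 7 libraries, 4 WT and 3 cKO, each from an independent animal per the labels. Per the labels' protocols, RNA was bound to poly-T beads, fragmented, copied with random hexamers and prepared with a NEBNext Ultra kit, with no step that keeps the strand. Reads of a gene and of an overlapping gene on the opposite strand therefore cannot be told apart. The authors deposited 1 table of raw read counts per feature, in whole numbers and not normalized. HISAT2, StringTie, featureCounts and the genome build mm39 are named, per the submitters' processing notes, without roles, and their versions and settings are not given in the sources used here. Such counts depend on how reads that match several places were treated, which bears on pseudogenes and on gene families such as trypsins, amylases, globins and histones. Columns were matched to samples by group and replicate number, and no column of per-sample values was left unused.

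The table held 27138 features, of which 26823 carry Ensembl gene identifiers and 315 only a running number. The latter took 0.206% of the counts, and 236 of them were tested. Gene symbols were found for 26764 identifiers, 59 had none, and 14 symbols were shared by several identifiers, where the symbol stayed with the identifier of the highest mean count. The reference annotation was GENCODE M21 on GRCm38, another build than the one named by the submitters, so it was used only for names, biotypes, chromosomes and which genes are neighbours, and no coordinates are given. Totals per library were 14883918 to 17767373 counts. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 11.1 to 50.8), so none was treated as a repeat of another.

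Counts were tested with edgeR 4.0.16 in R 4.3.3. Features were filtered with filterByExpr on the group, which left 16910, scaled with TMM factors (0.952 to 1.04), and fitted with estimateDisp, glmQLFit with robust estimation and glmQLFTest on a design with the group as its only term. A feature counted as changed at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.218 and the prior degrees of freedom 3.97. SEs were derived from the fitted coefficient and the F statistic, and 95% intervals from these with the total degrees of freedom. CPM values used TMM-scaled totals, and log2 CPM a prior count of 2. A group at 0 counts was given a floor of 3 counts over the group. Such floors and counting intervals cover counting error only, since PCR copies are not independent molecules. Group differences of single values were also tested by an exact two-sided permutation test over the 35 ways to divide 7 libraries into 4 and 3.

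The 32 gene lists were 7 for pancreatic lineages (digestive enzymes and zymogen granule proteins, acinar transcription factors, multipotent progenitor and trunk factors, duct genes, endocrine progenitor genes, beta cell genes, and alpha, delta, PP and epsilon cell genes), 11 for other cell types, 9 for programs and 5 for sample quality and embryo sex. Of their 527 entries 519 were matched, 487 of them tested. Lists with 5 or more tested genes, 29 in all, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named 2610035D17Rik, then up to 15 genes in each direction past the threshold with separated groups, a mean of at least 1 CPM and a symbol that is not a predicted-gene or clone name, the 2 members of each list with the smallest p, and Sox9, Pdx1, Ptf1a, Ptpn11, Cpa1, Krt19, Neurog3, Ins2 and Gcg. Because fewer than 10 genes passed, it gave the 10 features with the smallest unadjusted p in place of those past the threshold, and these do not pass apart from unannotated feature 201. Members are named in the text only where they bear on a comparison, and the results of 2 genes are not reported here. The features listed with a running number are called unannotated features here, with that number.

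The test was run on simulated counts with the real means, library sizes and dispersions, in 5 simulations of cKO against WT over 16910 genes with 200 changed. It recovered 24% of genes changed 1.5-fold, 63.2% of those changed 2-fold, 86% of those changed 3-fold and 91.2% of those changed 4-fold, and 6.48% of its calls were false. The simulated genes were independent and had 10.4 prior degrees of freedom, more than the 3.97 of the real libraries, so these shares are optimistic. A list of 20 genes shifted 1.3-fold had an upward camera p under 0.05, without adjustment, in 5 of 5 simulations. At an adjusted p under 0.05, 0 of 145 unshifted lists were called, so the shifted list had met a looser threshold. These lists were random draws of independent genes, whereas the estimated correlation within real lists reached 0.96 (liver). They therefore do not show how often camera at the preset correlation calls unchanged real lists.

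Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), other filters, DESeq2 1.42.0, limma-voom, estimation that is not robust, the replicate number as a block over replicates 1 to 3 of each group, which leaves out WT replicate 4, the digestive enzyme and erythroid genes left out, embryo sex, a surrogate variable from sva 3.50.0 or the mesenchyme list as a covariate, thinning to the smallest library, a test against a fold change of 1.2, each library left out in turn, and a window of 500000 bases for the neighbours. Settings added after the data were seen left out the libraries highest in liver genes or those at the ends of the first principal component, used the liver list or the neuron and Schwann cell list as a covariate, or used 2 surrogate variables. List calls under any of these settings come from camera at the preset correlation only. Their adjusted p values therefore take the genes of a list as nearly independent. Further tests on the results used Python 3.11.15, SciPy 1.17.1 and statsmodels 0.14.6.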

Results

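The pancreas of mouse embryos at E15.5 was profiled by sequencing of polyadenylated RNA, with 4 WT and 3 cKO libraries that each came from an independent animal. WT embryos carried floxed alleles of 2610035D17Rik, the mouse ortholog of the human long non-coding RNA LINC00673, without Cre. The cKO embryos carried the same alleles with Pdx1-Cre, which recombines the locus in the pancreatic epithelium. The comparison asked how the transcriptome of the developing pancreas differs once this RNA is deleted. WT embryos had no Cre, so the effect of the deletion was measured together with any effect of Cre or of chromosomes inherited with it. The deposited table counted reads over 27138 features, with 14883918 counts in the smallest library (WT replicate 4) and 17767373 in the largest (WT replicate 1), and 16910 features had enough counts to be tested. The 10702 tested features above 10 CPM (read counts scaled to a common library total) had a median standard error (SE) of 0.115 on the log2 scale.

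The targeted gene, 2610035D17Rik (ENSMUSG00000087259), was lower in every cKO library than in every WT library. It is a long intergenic non-coding RNA gene with 4 annotated transcripts on the minus strand of chromosome 11 in the GRCm38 annotation. Its normalised read count was 8.65 ± 0.498 CPM in WT (SD, n = 4) and 2.55 ± 0.726 CPM in cKO (SD, n = 3). WT replicates 1 to 4 held 168, 147, 137 and 125 counts, and cKO replicates 1 to 3 held 34, 57 and 41. The fitted log2 fold change was −1.76 (SE 0.215, 95% interval −2.25 to −1.27), which left 29.5% of the WT level (95% interval 21.1% to 41.4%). The 2-sided exact permutation test of log2 CPM over the 35 ways to divide the 7 libraries gave p = 0.0286, the smallest this design allows. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested features its adjusted p was 0.0902, above the threshold of 0.05, and in DESeq2 it was 9.3e-10. Which part of the gene was deleted is not given in the sources used here, so how many of the remaining reads lie outside it was not analysed here. Pdx1-Cre recombines the locus in the epithelium, whereas a dissected pancreas also holds other cells. How many of the remaining reads came from those cells was not measured. They would also dilute any change confined to the epithelium.

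Few other transcripts separated the groups. The only feature past the threshold with edgeR was unannotated feature 201, one of 315 features that carry a running number in place of an Ensembl identifier and whose position was not analysed here. It had 0 counts in all 4 WT libraries and 214, 394 and 441 counts in the cKO libraries, or 20.1 ± 6.49 CPM (SD, n = 3). Against a floor of 3 counts over the WT group it was at least 449-fold higher in cKO (edgeR adjusted p = 0.0463, Benjamini-Hochberg, and exact permutation p = 0.0286). This feature was picked by its p, and 0 counts in every WT library alone fix its exact p, which therefore adds no support. Its adjusted p rose to 0.115 without WT replicate 2, 0.161 without WT replicate 4 and 0.272 without cKO replicate 2 or cKO replicate 3, which ended the call although every WT library was at 0 counts. It was 0.0543 with DESeq2 size factors, 0.057 with library totals, 0.0538 with a filter at 1 CPM, 0.0654 with estimation that is not robust and 0.409 with embryo sex as a covariate. edgeR called 0 features lower in cKO. At an unadjusted p under 0.05 it listed 113 features higher and 121 lower, 234 in all where chance gives 846, and limma-voom called 1. The groups did not overlap for 460 features, or 2.72% of those tested, where chance gives 5.71%.

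DESeq2 called 13 features, 2 higher and 11 lower in cKO, with Benjamini-Hochberg adjustment. The higher ones were unannotated feature 201 and Gm7324 (log2 fold change 2.44, SE 0.305; 0.824 ± 0.223 CPM in WT and 4.49 ± 1.16 CPM in cKO). Among the lower ones, Ffar2, a receptor for short-chain fatty acids, had 90.6 ± 17.6 CPM in WT (SD, n = 4) and 39.7 ± 8.34 CPM in cKO (SD, n = 3), a log2 fold change of −1.19 (SE 0.192, DESeq2 adjusted p = 3.12e-06). Pik3r5, a regulatory subunit of phosphoinositide 3-kinase gamma, had 9.38 ± 1.52 CPM in WT and 4.41 ± 0.438 CPM in cKO (log2 fold change −1.09, SE 0.184). Hbb-y, an embryonic beta-like globin, had 16.7 ± 4.46 CPM in WT and 5.37 ± 1.49 CPM in cKO (log2 fold change −1.63, SE 0.274), and unannotated feature 328 had 6.76 ± 1.17 CPM and 2.20 ± 0.604 CPM (log2 fold change −1.61, SE 0.246). Aqp4, a water channel chosen after its values were seen, had 60.4 ± 13.0 CPM in WT and 31.6 ± 5.41 CPM in cKO (log2 fold change −0.93, SE 0.177). The pseudogenes Gm4815 (log2 fold change −4.01, SE 0.468) and Gm48496 (−2.06, SE 0.319) were near the lower limit of detection, as was the pseudogene Hist1h2al, with 94 counts over the WT libraries and 1 over the cKO libraries (ratio 73.1, 95% counting interval 12.8 to 2920). Reads of such copies can be shared with near-identical genes, so their values are uncertain. With edgeR these 8 annotated genes did not pass, with Benjamini-Hochberg adjusted p between 0.0902 and 0.909.

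**Figure D1:**
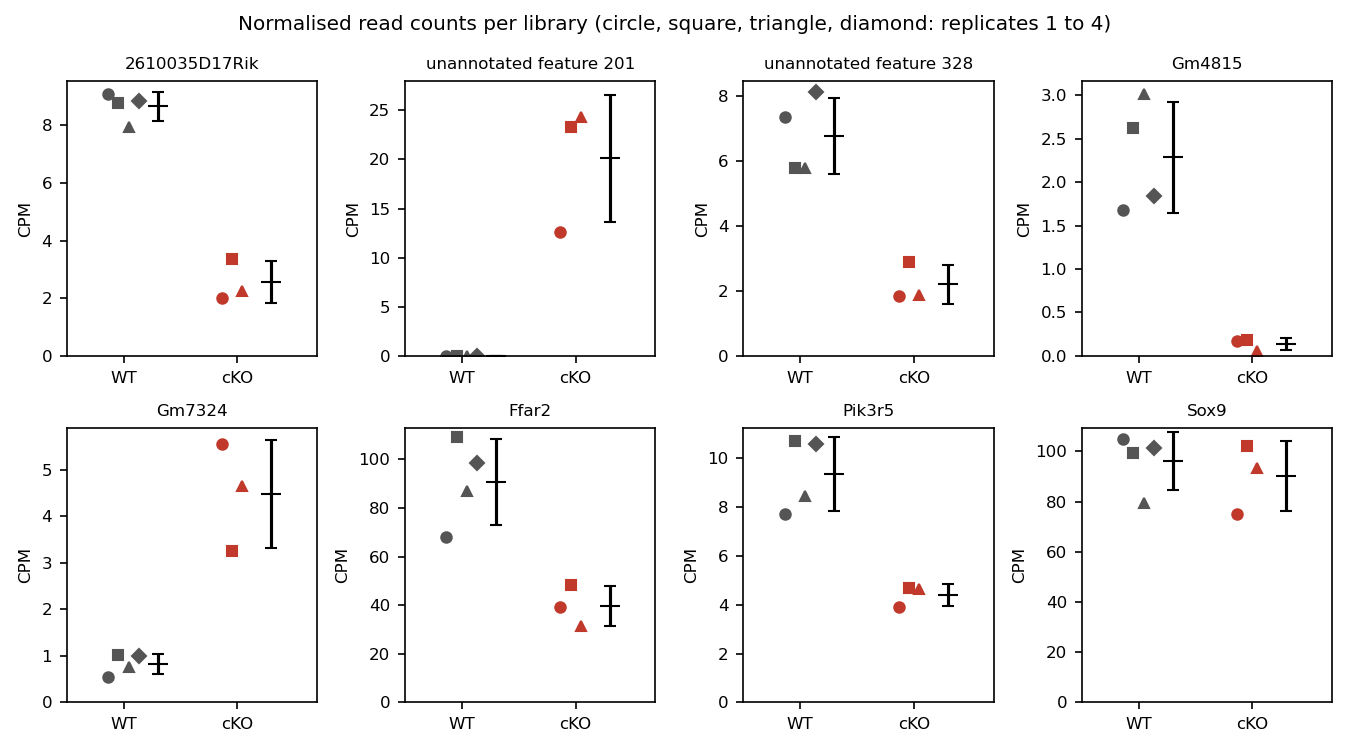
Normalised read counts (CPM, vertical axes from 0) of 8 features in the 4 WT (grey) and 3 cKO (red) libraries, with a marker shape per replicate and the mean and SD of each group in black. 2610035D17Rik lies at 8.65 CPM in WT and 2.55 CPM in cKO on average, unannotated feature 201 is at 0 in each WT library, and the Sox9 values of the groups overlap.

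Of the tested genes of the pancreatic lineages, 0 passed the threshold with edgeR, although the intervals leave room for shifts in single genes. The largest lay in Ctrc, a chymotrypsin, whose 30.0 ± 30.9 CPM in WT (SD, n = 4) and 99.2 ± 30.4 CPM in cKO (SD, n = 3) did not overlap (log2 fold change 1.72, 95% interval −1.02 to 4.47). The progenitor factor Sox9 had 96.2 ± 11.5 CPM in WT (SD, n = 4) and 90.1 ± 13.9 CPM in cKO (SD, n = 3), a log2 fold change of −0.09 (SE 0.131, 95% interval −0.39 to 0.20). The pancreatic master regulator Pdx1 gave a log2 fold change of −0.11 (95% interval −0.47 to 0.26), the acinar regulator Ptf1a 0.20 (−0.16 to 0.57) and the duct keratin Krt19 0.15 (−0.17 to 0.48). The endocrine progenitor factor Neurog3 gave −0.12 (−0.38 to 0.14), the hormone genes Ins2 and Gcg 0.30 (−0.23 to 0.83) and 0.13 (−0.13 to 0.40), and the zymogen gene Cpa1 −0.20 (−0.80 to 0.40). By list, 10 of 19 multipotent progenitor and trunk factors were higher in the fit (median log2 fold change 0.01), 4 of 8 acinar transcription factors (−0.03), 15 of 23 duct genes (0.06), 6 of 22 endocrine progenitor genes (−0.06) and 9 of 15 alpha, delta, PP and epsilon cell genes (0.06). None of these 5 lists was called by camera (adjusted p between 0.439 and 0.909). The multipotent progenitor list was called upward without cKO replicate 1 (median 0.0595, adjusted p = 0.0267) and had a median of −0.14 without cKO replicate 2. In settings chosen after the data were seen, duct genes were called upward without the libraries highest in liver genes (0.114, adjusted p = 0.0089). Without the ends of the first principal component, duct genes and the multipotent progenitor list were called upward (0.0595 and 0.0926, adjusted p = 0.00467 and 0.00449). These ends are WT replicate 2 and cKO replicate 1, the highest WT and lowest cKO library for the multipotent progenitor list. The rise of that list therefore followed from the choice of libraries. Adjusted over the list alone, 0 members of the 7 pancreas lists passed.

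Digestive enzymes and zymogen granule proteins leaned upward in cKO as a group, with 28 of 32 members higher in the fit and a median log2 fold change of 0.22. Beta cell genes leaned the same way, with 14 of 19 members higher and a median of 0.12. Ero1lb, an endoplasmic reticulum oxidase that folds proinsulin, had 96.1 ± 27.7 CPM in WT and 143 ± 22.6 CPM in cKO, and the islet amyloid gene Iapp had 97.5 ± 15.1 and 120 ± 18.9 CPM. Neither passed the threshold. camera with a preset correlation of 0.01 gave each list an adjusted p of 0.000336 (Benjamini-Hochberg over 29 lists), and with an estimated correlation the adjusted p was 0.97 for each. Digestive enzymes took 4.64% to 4.84% of the counts of WT replicates 1 to 3 and 4.71% of those of cKO replicate 3, but 8.84% in WT replicate 4, 7.82% in cKO replicate 1 and 6.35% in cKO replicate 2. The digestive enzyme median was −0.15 without cKO replicate 1 (adjusted p = 0.867), 0.64 without WT replicate 4, and 0.05 to 0.09 without WT replicate 1, 2 or 3 (adjusted p = 0.051, 0.106 and 0.0755), so 4 of the 7 libraries could each end the call. The beta cell call ended without WT replicate 2 (median 0.04, adjusted p = 0.0914) or cKO replicate 2 (0.11, adjusted p = 0.0519), and its median was 0.18, 0.21 and 0.25 without WT replicate 1, WT replicate 4 and cKO replicate 3. The digestive enzyme median was 0.45 without cKO replicate 3. In settings chosen after the data were seen, it was 0.355 without both WT replicate 4 and cKO replicate 1 (adjusted p = 1.63e-14 at the preset correlation). That fit left cKO replicate 2 and cKO replicate 3, and the share in cKO replicate 3 was within that of WT replicates 1 to 3. With the liver list as a covariate the digestive enzyme median was 0.0754, which ended the call (adjusted p = 0.172).

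Among markers of the other cell types a dissected pancreas can hold, 13 of 13 liver genes were higher in the cKO fit (median log2 fold change 0.94), 8 of 10 mesothelial genes (0.21) and 14 of 15 macrophage and leukocyte genes (0.11). camera with the preset correlation called these 3 lists (adjusted p = 0.004, 0.0353 and 0.0109), and the adjusted p was 0.97 for each with an estimated correlation. The size of the liver difference depended on single libraries. Alb, serum albumin, had 354 CPM in WT replicate 4 and 689 CPM in cKO replicate 1 but 8.59 to 31.0 CPM in the other 5 libraries, and without cKO replicate 1 the liver median was −1.51 and called in the opposite direction (adjusted p = 0.0367). That median was 2.41 without WT replicate 4, 1.43 without cKO replicate 2 and 1.44 without cKO replicate 3. It was 0.211 and still called upward without both WT replicate 4 and cKO replicate 1 (adjusted p = 0.0334, a setting chosen after the data were seen). The liver call ended without WT replicate 1 or WT replicate 3 (adjusted p = 0.244 and 0.103), the macrophage call without WT replicate 1, WT replicate 2 or cKO replicate 1 (0.365, 0.128 and 0.524) and the mesothelial call without WT replicate 1, WT replicate 2, cKO replicate 1 or cKO replicate 3 (0.282, 0.136, 0.598 and 0.666). The macrophage median was 0.0478, 0.0459 and 0.0115 in these lost calls, in that order, and the mesothelial median 0.148, 0.0987, 0.0767 and 0.172. The macrophage median was 0.24 without WT replicate 4 and 0.25 without cKO replicate 3, and the mesothelial median 0.45 without cKO replicate 2. Lists that were not called were mesenchyme (8 of 19 higher, median −0.03), smooth muscle (6 of 10, 0.16), endothelium (5 of 15, −0.01), erythroid cells (10 of 12, 0.34), neurons and Schwann cells (6 of 15, −0.06) and spleen (3 of 7, −0.05), with adjusted p between 0.0752 and 0.909. Single libraries set some of these results too, in fits where camera was run at the preset correlation only. The estimated correlation was 0.88 for neurons and Schwann cells. The preset correlation takes these genes as nearly independent, so small adjusted p values there overstate the evidence for a difference between the groups. Neurons and Schwann cells were called lower without WT replicate 2 (median −0.314, adjusted p = 0.000279) or cKO replicate 1 (−1.10, 1.5e-10). Their median was positive but not called without WT replicate 1 (0.30), WT replicate 3 (0.0255), cKO replicate 2 (0.127) or cKO replicate 3 (0.181). Erythroid cells were called higher without WT replicate 4 (0.618, 0.0304) and lower without cKO replicate 1 (−0.413, 0.0118). Smooth muscle was called higher without WT replicate 3, WT replicate 4 or cKO replicate 2 (0.177, 0.201 and 0.212, with adjusted p = 0.0335, 0.0268 and 0.00657). Hbb-y was the only erythroid member past the threshold adjusted over the list alone (adjusted p = 0.00288), and it was lower in cKO where 10 others were higher. Stomach epithelium (median 0.01) and intestinal epithelium (0.08) had 4 tested members each, too few for the set test.

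**Figure D2:**
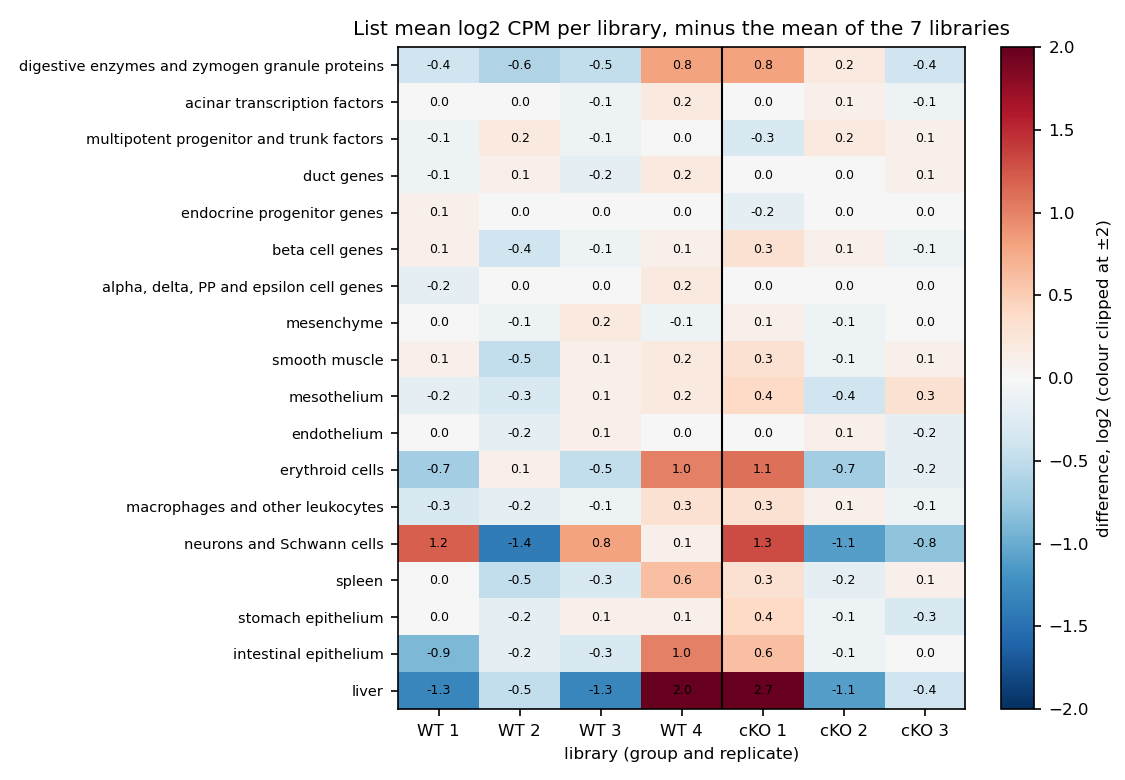
Mean log2 CPM of the pancreas and other cell type lists in each library, as the difference from the mean of the 7 libraries (log2 units, colours clipped at ±2 and the value printed in each cell). The black line parts WT from cKO, and the liver list stands highest in WT replicate 4 and cKO replicate 1.

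Of the cellular programs, targets of the tumour suppressor p53 were higher in 11 of 15 members (median log2 fold change 0.11, camera adjusted p = 0.00135, and adjusted p = 0.93 with an estimated correlation). Its member with the smallest p was Ccng1, cyclin G1, with 115 ± 4.01 CPM in WT (SD, n = 4) and 139 ± 13.7 CPM in cKO (SD, n = 3), which did not pass the edgeR threshold (adjusted p = 0.145 adjusted over the list alone). Without cKO replicate 2 the p53 median was 0.03 and the call ended (adjusted p = 0.204), and it was 0.07 without WT replicate 2 and 0.17 without cKO replicate 3. The remaining programs were not called by camera: S phase and mitosis (3 of 24 higher, median −0.05), interferon-stimulated genes (10 of 21, −0.02), MAPK feedback and immediate targets (6 of 15, −0.04), Wnt targets (6 of 10, 0.01), Notch targets and ligands (4 of 14, −0.05), YAP targets (1 of 12, −0.06), the unfolded protein response (13 of 22, 0.04) and hypoxia and glycolysis (10 of 18, 0.02), with adjusted p between 0.0659 and 0.95. S phase and mitosis was called lower without WT replicate 1, WT replicate 3, WT replicate 4 or cKO replicate 3 (medians −0.0719, −0.0781, −0.105 and −0.101, with adjusted p = 0.0425, 0.0242, 0.0117 and 0.00969). The unfolded protein response was called higher without WT replicate 4 (median 0.109, adjusted p = 0.000206) or cKO replicate 3 (0.131, 0.00439). Among lists that follow sample quality, 30 of 31 cytosolic ribosomal protein genes were higher in the cKO fit (median 0.13, camera adjusted p = 7.77e-07) and 11 of 13 mitochondrially encoded genes (median 0.14, camera adjusted p = 0.0155), and with an estimated correlation the adjusted p was 0.97 for both. The ribosomal call ended without cKO replicate 1 (median 0.04, adjusted p = 0.16) and the mitochondrial call without WT replicate 1, WT replicate 3 or cKO replicate 3 (adjusted p = 0.807, 0.0887 and 0.666). The mitochondrial median was 0.00122, 0.10 and 0.0207 in these lost calls, in that order. Without WT replicate 4 the mitochondrial median was 0.28, and without cKO replicate 3 the ribosomal median was 0.20. Dissection stress genes (9 of 17 higher, median 0.00025) and replication-dependent histones (6 of 9, 0.15) were not called (adjusted p = 0.909 and 0.0659), although Hist1h2bc, a core histone gene, passed adjusted over the list alone (log2 fold change 0.45, adjusted p = 0.0374). The 4 Y-linked genes of the sex-linked list had a median of 0.42, and WT replicate 2 was the only library with Xist (20326 counts) and without Y-linked reads (0 counts, which allows up to 0.178 CPM).

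**Figure D3:**
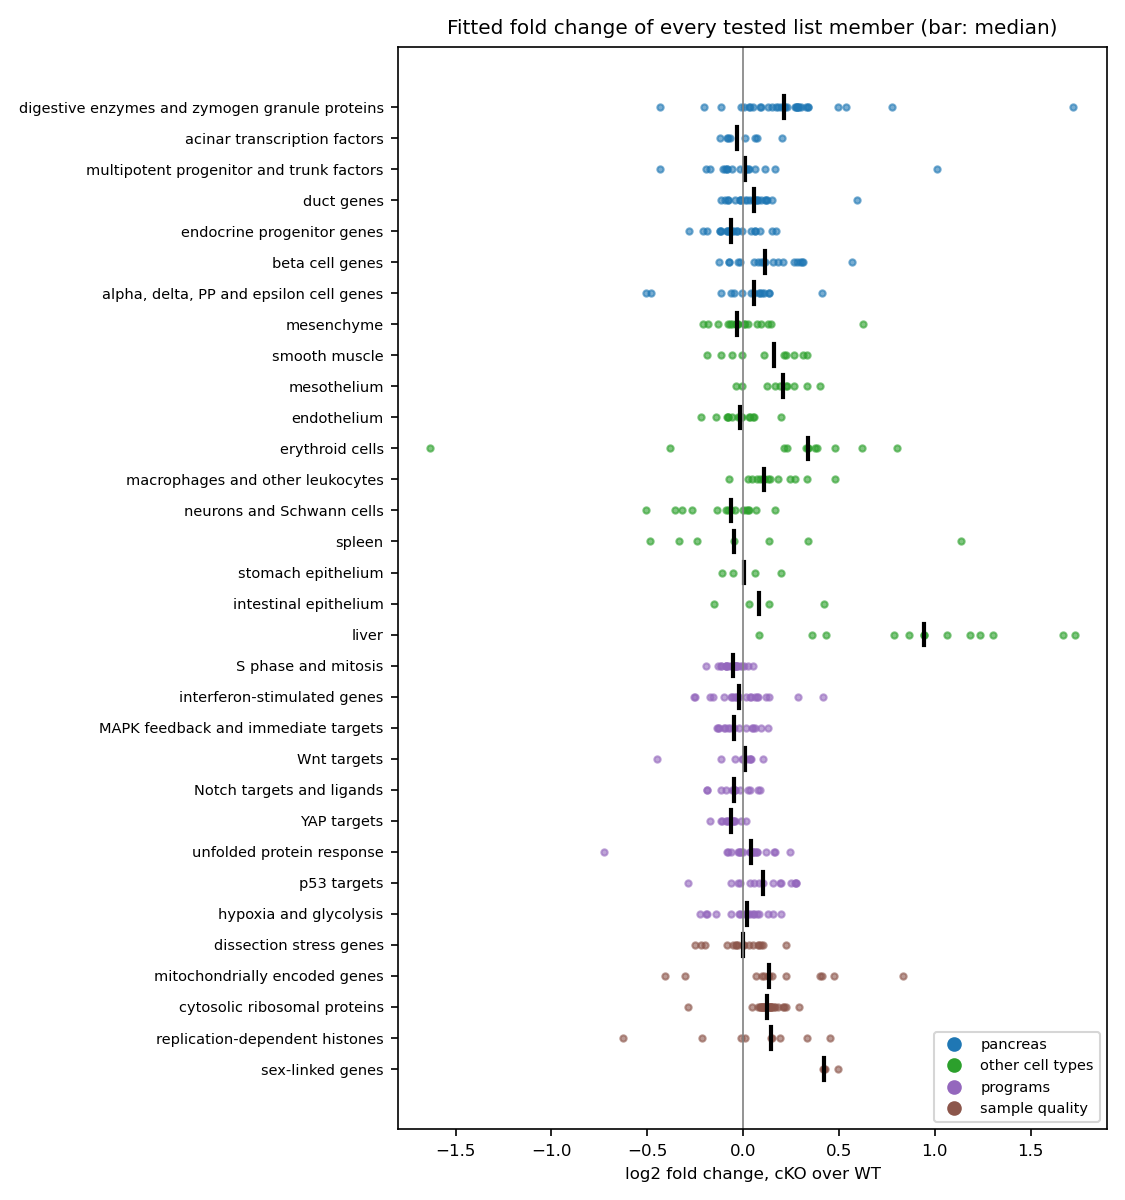
Fitted log2 fold change of cKO over WT (horizontal axis) for every tested member of each gene list (1 point per gene, coloured by kind of list), with the list's median as a black bar. Medians lie close to 0 for most lists, with the liver list at 0.94, sex-linked genes at 0.42, erythroid cells at 0.34, digestive enzymes at 0.22 and mesothelium at 0.21.

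Over all lists, 0 of 487 tested members passed the threshold over all genes with edgeR, whereas DESeq2 called Hbb-y. camera called 8 of 29 lists, all upward in cKO. None held with an estimated correlation, for which the smallest adjusted p was 0.93, or with fry. The median log2 fold change, the mean and the direction in camera differed in sign for acinar transcription factors (median −0.0298, mean 1.14e-05, upward), multipotent progenitor and trunk factors (median 0.011, mean 0.0119, downward), alpha, delta, PP and epsilon cell genes (median 0.0566, mean −0.00387, upward), mesenchyme (median −0.0289, mean 0.0121, downward), spleen (median −0.0453, mean 0.0717, upward), interferon-stimulated genes (median −0.0187, mean 0.00383, upward), Wnt targets (median 0.0122, mean −0.0365, upward), hypoxia and glycolysis (median 0.0226, mean −0.000227, upward) and dissection stress genes (median 0.00025, mean −0.0135, upward).

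Genes near the deleted locus were compared next, because long non-coding RNAs can act on their neighbours. None of the 25 tested genes within 2 Mb of 2610035D17Rik in the GRCm38 annotation passed the threshold adjusted over the neighbours alone with edgeR (smallest adjusted p = 0.958). Their log2 fold changes ran from −0.35 to 0.42, with 12 higher and 13 lower in cKO. Sox9 is among them, with the values given above. Fam104a had the smallest unadjusted p, with a log2 fold change of 0.20 (95% interval 0.01 to 0.40). Sstr2, a somatostatin receptor, gave 0.14 (−0.29 to 0.57), and the potassium channel gene Kcnj2 −0.02 (−0.43 to 0.39). Ptpn11, which encodes the phosphatase SHP2 and whose protein has been linked to human LINC00673, had 192 ± 13.6 CPM in WT (SD, n = 4) and 183 ± 22.9 CPM in cKO (SD, n = 3), a log2 fold change of −0.07 (95% interval −0.31 to 0.16). Protein was not measured here.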

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

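Values of the 4 WT libraries were screened for a library far from the other 3, by Dixon's ratio, and 13 of 116 values stood out where chance gives about 1 in 20, or 5.8. The values are not independent, because lists and shares hold genes that were also screened singly. An excess over 5.8 can therefore come from repeats of a few differences. Leaving out each library was planned, but the test of cKO replicate 1 as an explanation and the fit without both libraries were chosen after the result was seen. WT replicate 4 held 8 of the 13 values. In the deposited table its column carries another number beside the group name (7) than the other 6 libraries do (6), and what that number stands for is not given in the sources used here. Its normalised read counts were 1334 CPM for the elastase gene Cela1 (699 to 763 CPM in the other WT libraries), 8831 CPM for the carboxypeptidase gene Cpa1 (4576 to 4972 CPM), 780 CPM for the insulin gene Ins2 (430 to 462 CPM) and 6.08 CPM for the plasma protein gene Apoh (0.270 to 0.477 CPM). Its digestive enzyme list had a mean log2 CPM of 8.02 (6.59 to 6.74 in the others) and its unfolded protein response list 7.70 (7.23 to 7.29). Digestive enzymes took 8.84% of its counts (4.64% to 4.84%) and its 10 most abundant genes 10.9% (7.20% to 7.73%). WT replicate 2 held the other 5 values: 208 CPM for the replication gene Mcm2 (176 to 178 CPM), 7.16 mean log2 CPM for S phase and mitosis (6.91 to 6.95), 3.34 for smooth muscle (3.95 to 4.02), 0 CPM for the Y-linked gene Uty (22.2 to 23.7 CPM) and −3.08 for the sex-linked list (5.19 to 5.41).

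The higher digestive enzyme values in cKO were weighed against 3 explanations. A distortion by scaling is argued against by the list's median log2 fold change of 0.212 or more with library totals or DESeq2 size factors in place of TMM. The weight of cKO replicate 1 cannot be told apart from a shift in the others: the median was −0.15 without it, but 0.638 without WT replicate 4 and 0.355 without both (camera adjusted p = 1.63e-14). That adjusted p takes the list's genes as nearly independent, whereas their estimated correlation was 0.76. In the fit without both, cKO replicate 2 had a mean log2 CPM of 7.38 and cKO replicate 3 of 6.75. WT replicates 1 to 3 had 6.59 to 6.74, so the rise rested mainly on cKO replicate 2. The libraries are too few to choose between these readings. A higher expression in cKO embryos cannot be told apart from this spread: the exact permutation p of the list means was 0.514, and the group difference of 0.357 was small beside the range of 1.43 between WT libraries. The bound set for that test beforehand, an exact p above 0.2, was met but was wrong as a bound, because a shift of this size could not have been seen at that spread.

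Unannotated feature 201 had 0 counts in the 4 WT libraries and 214 to 441 in each cKO library. Among the 35 ways to divide the libraries, 3 gave a feature at 0 counts in 4 libraries and at 10 or more in each of the other 3, with 1 such feature at most in any other division, so chance cannot be excluded from that count. The other divisions had far fewer reads, 29 to 50 counts for another unannotated feature and 11 to 23 counts for Sox1. A transcript of the Cre transgene or of the recombined locus is a candidate source, since a total of 0 counts over the WT libraries is what it predicts, but any sequence inherited with Cre predicts the same and the design confounds them. The only genome build named is mm39, and whether a Cre sequence was added to it is not given in the sources used here. Without one, only mouse sequence within the transgene could have been counted. The position of the feature was not analysed here, which keeps this open.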

How the results depend on the processing

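The log2 fold change of 2610035D17Rik ran from −2.02 to −1.61 over 27 settings and was negative in all of them, but its adjusted p ran from 9.3e-10 to 0.631 and was under 0.05 in 6: no filter on low counts (−1.76, adjusted p = 0.0121 with edgeR), DESeq2 (−1.76, 9.3e-10), replicate block (−1.78, 0.0454), 1 surrogate variable (−1.81, 0.0384), and, chosen after the data were seen, 2 surrogate variables (−1.80, 0.0158) and the neuron and Schwann list covariate (−1.81, 0.0453). Leaving out each library in turn gave −2.02 to −1.61, with adjusted p of 0.191 to 0.631. Unannotated feature 201 passed in 18 settings. The count of changed features was 1 (1 higher, 0 lower). It was 0 (0 higher) with DESeq2 size factors, library totals, a filter at 1 CPM, estimation that is not robust or the embryo sex covariate, 4 (2 higher, 2 lower) without a filter or with 1 surrogate variable, 13 (2 higher, 11 lower) with DESeq2, and 0 to 3 (0 to 3 higher, 0 to 2 lower) when each library was left out in turn. Settings chosen after the data were seen gave 7 (2 higher, 5 lower) with 2 surrogate variables, 3 (1 higher, 2 lower) without the ends of the first principal component or with the neuron and Schwann list covariate, and 1 without the libraries highest in liver genes or with the liver list covariate. Whether the replicate numbers pair the embryos could not be settled. The deviations of same-numbered libraries correlated at 0.28, 0.42 and 0.06. For cKO replicates 1 and 2 the same-numbered WT library correlated best, but cKO replicate 3 correlated best with WT replicate 2 (0.30). The block covered replicates 1 to 3 and so left out WT replicate 4. It gave 13 features (6 higher, 7 lower), 7 of them shared with DESeq2, against 0 without WT replicate 4 alone. Of its 12 called lists, 11 were also called without WT replicate 4 alone. Neurons and Schwann cells were called lower only with the block (−0.326, adjusted p = 0.0135, against 0.194), and erythroid cells only without WT replicate 4 alone (0.0304 against 0.145). camera called 8 lists, 6 without a filter (mesothelium ended at 0.0879 and mitochondrial genes at 0.0511), 5 with the embryo sex covariate (digestive enzymes, beta cell genes, mesothelium and macrophages ended at medians of 0.0914, 0.037, 0.135 and 0.0577 and adjusted p of 0.0596, 0.0596, 0.0723 and 0.0755, and neurons and Schwann cells were called lower at −0.17 and 0.00155), 0 with an estimated correlation, 0 with fry, 4 to 12 when each library was left out in turn and, in settings chosen afterwards, 5 without the ends of the first principal component, 4 with the liver list covariate, and 9 without the libraries highest in liver genes or with the neuron and Schwann list covariate, each of which kept 7 of the 8. Gained calls in these settings included neurons and Schwann cells, lower without the libraries highest in liver genes (−1.19, 3.48e-10), erythroid cells, lower with the liver list covariate (−0.297, 0.000543), and, with the neuron and Schwann list covariate, smooth muscle, higher (0.178, 0.00229), and S phase and mitosis, lower (−0.0884, 0.0088). The embryo sex covariate (log2 of Xist over Y-linked counts) was 15.3 in WT replicate 2 and −11.1 to −8.63 in the other libraries. It nearly marks that library alone, and leaving the library out ended the same lists and also called neurons and Schwann cells lower. Embryo sex and this library cannot be told apart. Genes that changed sign were uncalled. In the block fit Chac1 was at 0.138 and Cpa1 at 0.0647, both of which turned without WT replicate 4 alone (0.053 and 0.077). Leaving out each library in turn gave log2 fold changes from −0.174 to 0.0255 for gene Ednrb (0.000707 without WT replicate 1), −0.0671 to 0.152 for gene Cldn18 (−0.0533 without cKO replicate 2), −0.275 to 0.014 for gene Lgals4, −1.51 to 2.28 for gene Apoh, −0.741 to 1.48 for gene Trf, −1.06 to 0.053 for gene Chac1, −0.295 to 0.077 for gene Cpa1, −0.195 to 0.0294 for gene Sox9, −0.218 to 0.0834 for gene Pdx1, −0.145 to 0.0302 for gene Ptpn11 and −0.221 to 0.00437 for gene Neurog3. The turned values came without WT replicate 1 (Ednrb, Cldn18), WT replicate 3 (Ednrb, Lgals4), WT replicate 4 (Chac1, Cpa1), cKO replicate 1 (Apoh, Trf, Sox9, Pdx1, Ptpn11, Neurog3) or cKO replicate 2 (Cldn18). List medians ran from −0.15 to 0.638 for digestive enzymes and −1.51 to 2.41 for liver, both lowest without cKO replicate 1, and the mitochondrial list turned in direction at a median of 0.00122 without WT replicate 1 (0.284 at most). Without the ends of the first principal component the digestive enzyme, liver, mesothelial and macrophage medians were −0.343, −1.80, −0.033 and −0.0307, the beta cell and ribosomal calls ended (adjusted p = 0.926 and 0.259), and neurons and Schwann cells were called lower (−1.41, 9.59e-34). Those ends, WT replicate 2 and cKO replicate 1, had the lowest WT and highest cKO mean log2 CPM of the neuron list (3.04 and 5.78). Leaving out both had to lower that list, so this call shows only the choice of libraries. Of 1621 values of named genes and of the number of called lists under the alternatives, 1574 kept direction and side of the threshold or, for the number, stayed within 1.5 times. Of these named genes only unannotated feature 201 was called in the main fit. For most values, keeping the side of the threshold was therefore nearly fixed beforehand and says little about robustness. The 8 neighbours within 500000 bases gave 0 calls, as did the 25 within the wider window. The cause of these moves was not tested. Depth limits features such as Gm4815 and Hist1h2al, which had 7 counts or fewer over the cKO group.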

Other observations

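Of the tests in this part, those on any chromosome, on the segment around the targeted gene and on strain haplotypes were chosen after the results were seen. The largest differences between embryos did not follow genotype. Several members of the neuron and Schwann cell list, chosen after their values were seen, were high in WT replicate 1, WT replicate 3 and cKO replicate 1 and low in WT replicate 2, cKO replicate 2 and cKO replicate 3. Th, tyrosine hydroxylase, had 97.5, 67.2 and 109 CPM in the former and 3.10, 4.80 and 6.96 CPM in the latter, with 25.3 CPM in WT replicate 4. Dbh, dopamine beta-hydroxylase, had 164, 97.2 and 151 CPM against 1.85, 1.18 and 5.03 CPM, and the neurofilament gene Prph 155, 134 and 250 CPM against 14.9, 12.6 and 27.9 CPM. Not every member followed this division: Ednrb ran only from 40.6 to 60.8 CPM, and Sox10 had 22.8 CPM in cKO replicate 2 and 21.2 CPM in cKO replicate 1. Sox1 was detected in those 3 libraries alone, at 11 to 23 counts. Liver genes followed another division, with 454 CPM of Afp, alpha-fetoprotein, in WT replicate 4 and 664 CPM in cKO replicate 1 against 49.7 to 81.9 CPM in the other 5 libraries.

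Dividing the 7 libraries in all 35 ways showed how much of this exceeds the genotype. edgeR called 1 feature for the real groups, 15 of the 35 divisions called at least as many, and the highest other count was 307, with cKO replicates 2 and 3 and WT replicate 2 against the rest. The division of WT replicates 1 and 3 and cKO replicate 1 from the rest called 278. With DESeq2, 18 of the 35 divisions called at least the 13 features of the real one, up to 688. On the edgeR fits, camera at the preset correlation called at least the 8 lists of the real division in 21 of the 35, up to 18. Chance therefore cannot be excluded for any of these counts, and divisions that call far more features than the real one point to a structure of the samples other than genotype, and the divisions that called 278 and 307 part the libraries high and low in the neuronal genes above. At an unadjusted p under 0.05, the real division listed 234 features and the others 194 to 2794.

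Genes with an unadjusted p under 0.05 formed more neighbouring pairs than random draws of independent genes, although other divisions of the libraries did not exclude chance. Among the 221 with a known position other than the targeted gene, 146 pairs lay within 2 Mb in GRCm38 where 67.0 are expected, a ratio of 2.18, and 0 of 1000 random draws gave as many (permutation p = 0.000999, the smallest they can give). Overlapping genes and near-identical copies, whose reads can be shared, were not removed from these pairs. Of 277 stretches of 10 Mb, 2 held more such genes than expected for independent genes after Benjamini-Hochberg adjustment. Stretches were not tested in the other divisions of the libraries, so chance was not excluded for them. A stretch of chromosome 11 that does not hold the targeted gene had 11 among 103 tested genes (exact hypergeometric adjusted p = 3.32e-05), with Slfn5 and Ap2b1 lower and Scpep1 and Srsf1 higher in the cKO fit. A stretch of chromosome 13 had 6 among 44 (adjusted p = 0.00327), with Gpr137b and the pseudogenes Gm18562 and Gm48496 lower and Gpr137b-ps and the beta cell list's Ero1lb higher. In several of these, 1 WT library lay near or within the cKO values. Gm18562 had 0.649 CPM in WT replicate 1, close to the 0.532 to 0.608 CPM of the cKO libraries, and 9.73 to 12.6 CPM in WT replicates 2 to 4, and unannotated feature 188 followed it (1 count in WT replicate 1 and 214 to 342 in the others). Gpr137b-ps had 16.5 CPM in WT replicate 1, near the 17.1 to 18.2 CPM of cKO. Scpep1 in WT replicate 4 (77.6 CPM) and, elsewhere on chromosome 11, Sumo2 in WT replicate 4 (8.69 CPM) fell within the cKO range, while the other WT libraries had 41.1 to 43.7 CPM and 29.4 to 47.5 CPM. Of the 10 annotated genes that DESeq2 called, 4 lay on chromosome 13. These genes were chosen after their values were seen.

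As a hypothesis, stretches of chromosome of different strain origin that segregate among the embryos could give this pattern, but the test could not have shown it: the ratio of 2.18 is the observation that prompted it, shared regulation of neighbouring genes predicts the same, and strain was not given in the labels. GC content, length and level of chromosome 11 genes are argued against, because their odds ratio for an unadjusted p under 0.05 was 2.33 (95% interval 1.60 to 3.40) with those terms and 2.16 without. The chromosome 11 excess by itself (34 of 1309 genes, exact hypergeometric p = 0.00012) was as strong only in the real 1 of the 35 divisions (next 0.000324). That is the smallest share 35 divisions can give, and the hypergeometric test takes genes as independent, so chance was not excluded. Nor was it excluded for an excess on any chromosome (8 of the 35, down to 2.77e-10). Several of these 8, with that lowest hypergeometric p, were for mitochondrially encoded genes, whose list had an estimated correlation of 0.68. They are not a like comparison for a nuclear chromosome, but another division gave 1.7e-07 on chromosome 17. Chance was also not excluded for the ratio of neighbouring pairs (2 of the 35, highest other 2.34, with WT replicates 1, 2 and 4 against the rest). The excess rested on some choices of libraries and of test, with exact hypergeometric p = 0.0937 without WT replicate 1, 0.0415 without cKO replicate 1, 0.64 without the ends of the first principal component and 0.0926 in the test against a fold change of 1.2 (12 genes, 0.917% of those on chromosome 11 and 0.573% of the others). A segment around the targeted gene cannot be told apart from the rest of chromosome 11, at 2.38% of genes within 20 Mb and 2.74% beyond (Fisher's exact p = 0.726).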
